A study of Homo sapiens with 75 samples.

How the data were processed

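RNA was measured in 75 skin biopsies from people with hidradenitis suppurativa (HS), a chronic inflammatory disease of skin folds rich in hair follicles and apocrine glands. The biopsies span treatment with brodalumab, an antibody that binds the receptor subunit IL17RA and blocks signalling by IL-17A, IL-17F, IL-17C and IL-17E. Per the labels' protocols, punch biopsies of lesional skin (in a lesion), perilesional skin (beside it) and nonlesional skin (uninvolved) were taken with ultrasound to guide them. Total RNA was treated with DNase, made into libraries with a stranded mRNA kit and sequenced as paired ends on an Illumina instrument, per the labels' protocols.

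The deposited values were whole-number read counts per gene, without normalization, for 57905 Ensembl genes and 75 libraries. Per the submitters' processing notes, the tools included STAR 2.4.2a, Subread 1.5.0 and its counter featureCounts, and the genome build was GRCh37. Whether featureCounts used strand is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Counts of near-identical genes (DEFB4A and its copy, SERPINB3 and SERPINB4, the KRT6 genes, S100A7 and its relatives, the LCE1 and SPRR2 genes, HBA1 and HBA2, and immunoglobulin genes) are uncertain, since counting could split or drop shared reads. Symbols were taken from a table of Ensembl identifiers, which matched 51996 genes, and from the GENCODE release 29 annotation, which raised the number to 52338. That annotation is of another build (GRCh38) and was used for names alone. All coordinates are GRCh37 positions as the deposited file gives them.

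Total counts ran from 10.86 to 50.11 M per library, with a median of 34.75 M and a second lowest total of 18.61 M. No pair of libraries of the same group, the only pairs examined, agreed within sampling noise (lowest chi-square per degree of freedom 91.2), so each library was counted as 1 sample. The 497 genes that are Y-linked or are XIST or TSIX were left out of every test and score. Library titles carry 1 of 2 prefixes, samX (18 libraries) or samAx (57 libraries), whose meaning is not given in the sources used here. They were treated as a possible batch. The samX libraries held 9 baseline, 6 week 2 and 3 week 4 biopsies, and the samAx libraries 18 baseline, 9 week 4, 3 week 8 and 27 week 12 biopsies. Median totals were 28.0 M for samX and 37.5 M for samAx.

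The labels put the libraries into 15 groups (3 skin sites at 5 times). No label names the patient, so the libraries were treated as independent samples, and baseline and week 12 biopsies were not paired. Whether the order of titles links biopsies of different times was not examined. The p-values measure only the spread between these samples. The design, the gene lists, the rule for named genes and the alternatives fixed beforehand were fixed before the data were examined.

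For each of 17 comparisons, counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersion, TMM scaling, the filterByExpr filter on low counts), fitting only the groups compared, with 1 mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM (CPM) on TMM library sizes, given as mean ± SD over libraries; log2 fold changes are given ± SE. The comparisons were of the 3 sites at baseline and at week 12, of weeks 2, 4 and 12 with baseline within each site, and of the week 12 change in lesional or perilesional skin with that in nonlesional skin (an interaction contrast). Week 8 has 1 library per site and entered no test. Alternatives were RLE scaling, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, no filter, a mean CPM of at least 1, all 75 libraries in 1 fit, a fold of at least 2, the title prefix as a covariate, each prefix alone, a replicate block of 3 consecutive title numbers and, for weeks 2 and 4, each library left out in turn. Added after seeing the data were each baseline library left out in turn, and fits without the 3 libraries with fewer than 20000 detected genes or without the 2 libraries with a cornified layer score under 3.

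Of the 301 genes in 29 fixed lists, 297 were matched (not CCL18, MMP12, TRAC or PECAM1). The 13 pathway lists were IL-17 response of keratinocytes, IL-17 and IL-23 axis ligands and receptors, epidermal activation, cornified layer, type I interferon response, interferon gamma response, TNF, IL-1 and IL-6 inflammation, type 2 inflammation, complement, matrix metalloproteinases and tissue remodelling, lymphoid aggregate chemokines and receptors, proliferation, and immediate early response. The 16 cell type lists were B cells and plasma cells, T cells, neutrophils, macrophages and monocytes, dendritic and Langerhans cells, mast cells, fibroblasts, endothelium, eccrine and apocrine glands, sebaceous glands, adipocytes, hair follicle, melanocytes, smooth muscle, skeletal muscle, and red blood cells. Each list was tested against the other genes with camera (preset correlation 0.01), again with an estimated correlation, and on its own with fry, with adjustment over the lists of a comparison. A list score is the mean over members of log2(CPM + 1) per library. Scores were compared by exact two-sided permutation tests, adjusted over 29 lists, with 95% intervals from the same permutations. For 9 against 9 libraries there were 48620 groupings (smallest p 4.11e-05) and for 9 against 4 there were 715 (smallest p 0.0014). For 6 against 6 libraries, as among samAx libraries at baseline, a list on its own could not pass this adjustment.

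The rule for named genes took, for each baseline comparison of sites and each comparison of week 12 with baseline, the 8 largest and 8 smallest log2 fold changes among called genes with a mean CPM of at least 1. It left out immunoglobulin and T cell receptor segments, mitochondrial genes and genes known only by a clone name. It then took up to 4 called members per list by adjusted p, or the most abundant member where none was called, and IL17RA, IL17A, IL17F and IL17C throughout. Of the list members so taken, the text prints the first and others that fit its space. Of the genes the rule took, 2 are not reported here. The 3 ligands fell under the filter in several comparisons and were tested on log2(CPM + 1) by exact permutation, adjusted over 27 tests. This test was added after that was seen, and the levels printed beside it are means of CPM.

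Title numbers run in 25 sets of 3, with 1 library of each site at 1 time. Deviations from the group means were correlated within these sets. For week 12 lesional and perilesional skin all 9 pairs correlated above 0.1 (lowest 0.36, median 0.57, highest 0.84; median of other pairs -0.15), and the blocked result is given beside that comparison. List scores of that comparison were also tested within the 9 sets by exact two-sided sign flips (512), adjusted over 29 lists, an alternative added after seeing the data.

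The edgeR step was tested on simulated counts with 200 changed genes. For baseline lesional against nonlesional skin (17979 genes) it recovered 26% of 2-fold and 83% of 4-fold changes, and for week 12 against baseline in lesional skin (18092 genes) 17% and 80.8%. For week 4 against baseline in lesional skin (19136 genes) it recovered 2% and 31%, and for week 2 (20413 genes) 0% and 7%. The simulated counts were drawn for each gene independently, and the changed genes were taken at random among those with a mean CPM of at least 1. They lack the deviations that the genes of a real library share. These percentages therefore do not measure how often changes in the real libraries, or in inflammatory genes with a wide spread, would be called. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.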

Results

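Gene expression was measured by RNA sequencing in 75 skin biopsies of hidradenitis suppurativa (HS), taken before and during treatment with brodalumab, an antibody to the IL-17 receptor subunit IL17RA. The groups held 9 lesional, 9 perilesional and 9 nonlesional libraries at baseline and again at week 12, 4 of each site at week 4, 2 of each at week 2 and 1 of each at week 8. Total counts per library ran from 10.86 to 50.11 M. Immunoglobulin genes, the product of plasma cells, took a median of 6.54% of counts in lesional, 3.24% in perilesional and 0.9% in nonlesional skin at baseline, and up to 37.17% in 1 lesional library at week 2. Mitochondrial genes took a median of 4.96% of counts in lesional skin at baseline (2.73 to 22.15%), 5.31% in perilesional and 7.77% in nonlesional skin.

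**Figure D1:**
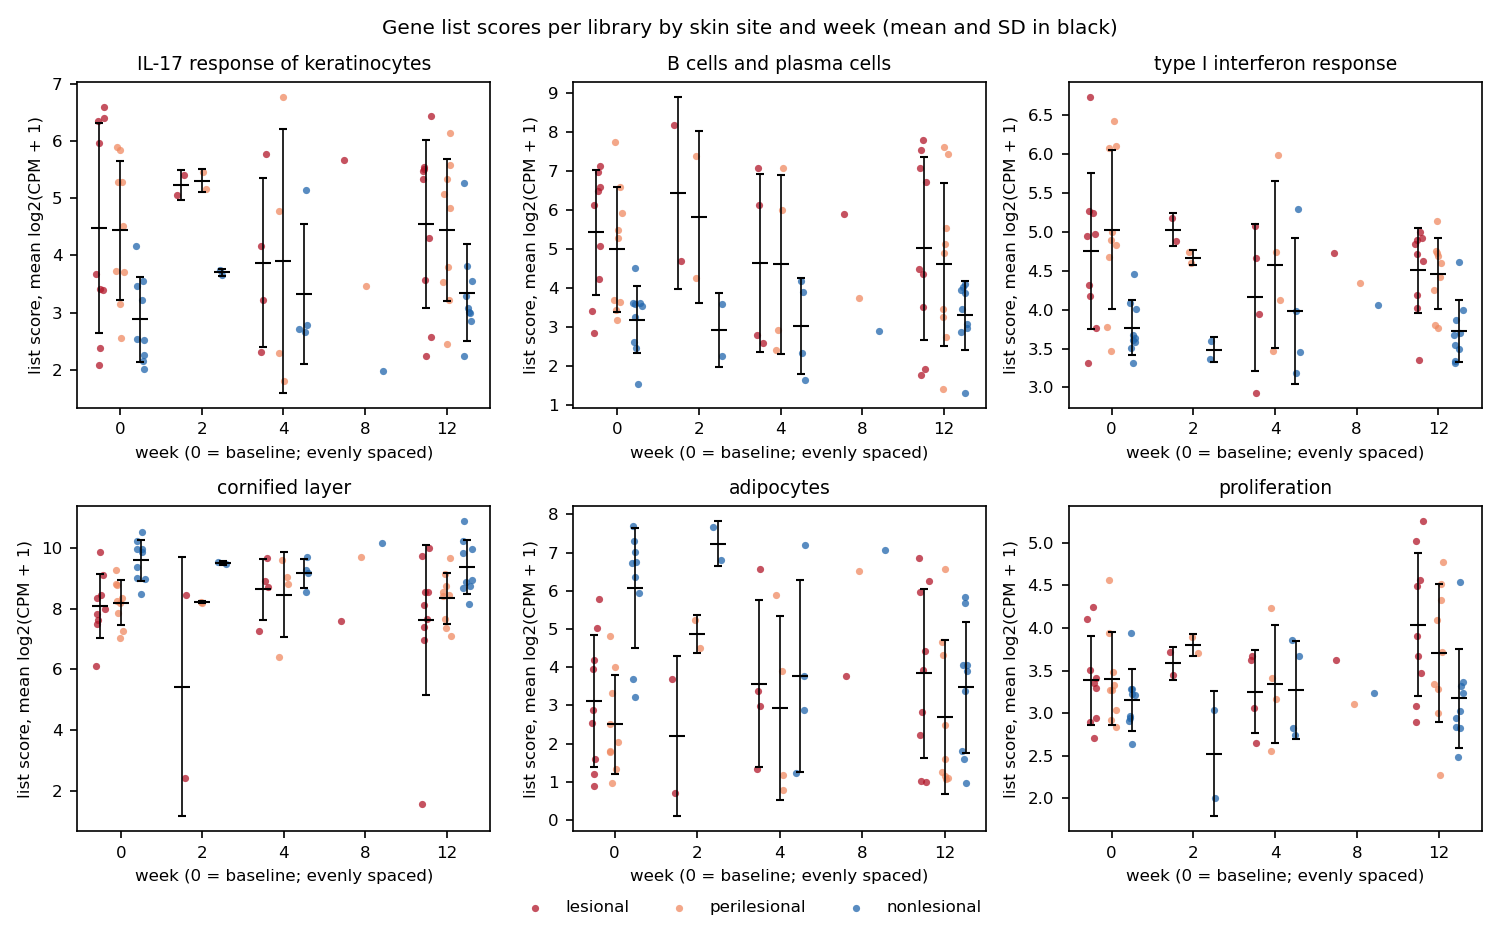
Scores of 6 gene lists (mean log2(CPM + 1) of the members) on the vertical axis against week of treatment on the horizontal axis (weeks evenly spaced, 0 is baseline), with 1 point per library for lesional, perilesional and nonlesional skin and the group mean and SD in black. At baseline the IL-17 response score was 4.47 in lesional and 2.88 in nonlesional skin, and at week 12 it was 4.55 and 3.35.

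The comparison of lesional with nonlesional skin at baseline addressed what marks a lesion before treatment. As lists, genes of B cells and plasma cells, of the IL-17 response of keratinocytes, of neutrophils and of fibroblasts were higher in lesional skin by camera, and those of the cornified layer, of adipocytes and of melanocytes lower. None of the 20 camera calls held with an estimated correlation (adjusted p 0.333 to 0.366 with an estimated correlation). The B cell surface gene MS4A1 (chromosome 11, 60223225 to 60238233), which encodes CD20, reached 30.4 ± 30.8 CPM in lesional against 0.801 ± 0.851 CPM in nonlesional skin (SD, n = 9 each; log2 fold change 5.25 ± 0.97, adjusted p = 0.0144). For this gene 8 of 9 lesional libraries lay above the nonlesional median. S100A7, an antimicrobial protein of keratinocytes induced by IL-17 (chromosome 1, 153430220 to 153433177), was at 1377 ± 1540 against 160 ± 166 CPM (3.13 ± 0.80, adjusted p = 0.0224). KRT10, a keratin of the differentiated epidermis (chromosome 17, 38974369 to 38978847), was at 7704 ± 5896 against 20710 ± 8064 CPM (-1.41 ± 0.41, adjusted p = 0.0334). Its call ended without nonlesional replicate 8 (adjusted p = 0.0595).

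Among the pathway lists, the IL-17 response of keratinocytes had 7 of 16 tested members higher over all genes tested and 14 adjusted over the list alone (median log2 fold change 3.12, camera adjusted p = 7.29e-05; adjusted p = 0.333 with an estimated correlation). CXCL1, a chemokine that attracts neutrophils (chromosome 4, 74735110 to 74736959), was at 40.8 ± 54.1 against 1.91 ± 2.08 CPM (4.43 ± 1.12, adjusted p = 0.0225). CXCL6, of the same family, had a log2 fold change of 4.21. Epidermal activation, the keratins and serpins of wounded or hyperproliferative epidermis, had 4 of 14 members higher, 10 adjusted over the list alone (2.13, adjusted p = 0.000507). SERPINB3, a protease inhibitor of squamous epithelium, had a log2 fold change of 3.59 ± 0.70 (adjusted p = 0.0144). The cornified layer had 5 of 14 members lower, 13 adjusted over the list alone (-1.43, adjusted p = 1.45e-08). Type I interferon response genes were higher in 8 of 14, 11 adjusted over the list alone (1.47, adjusted p = 6.12e-06). They included the antiviral genes MX2 (1.43 ± 0.31, adjusted p = 0.0153) and RSAD2 (2.50 ± 0.58). TNF, IL-1 and IL-6 inflammation had 5 of 12 higher and 10 adjusted over the list alone (1.81, adjusted p = 0.000972). TNFAIP6, a secreted protein made in response to TNF, was at a log2 fold change of 2.78. Interferon gamma response had 3 of 10 higher and 7 adjusted over the list alone (1.90, adjusted p = 0.004). Matrix metalloproteinases and tissue remodelling had 2 of 7 and 7 (3.21, adjusted p = 0.007), lymphoid aggregate chemokines and receptors 4 of 8 and 6 (1.89, adjusted p = 0.007), and complement 5 of 12 and 6 (0.75, adjusted p = 0.000742). The adjusted p of these called lists lay between 0.333 and 0.366 with an estimated correlation.

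The remaining pathway lists differed less. The IL-17 and IL-23 axis ligands and receptors had 1 of 6 members lower and 2 adjusted over the list alone (-0.46, camera adjusted p = 0.015), with score differences of -0.25 in samAx and 0.13 in samX libraries, the 2 series of library titles. No list-wide difference passed for type 2 inflammation (0.26, adjusted p = 0.915), proliferation (0.55, adjusted p = 0.2) or immediate early response (-0.09, adjusted p = 0.338). The 20 camera calls in this comparison, 13 up and 7 down, became 0 with an estimated correlation (adjusted p 0.333 to 0.366), and fry called 4.

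Cell type markers differed in both directions. B cells and plasma cells had 12 of 15 markers higher and 15 adjusted over the list alone (3.48, camera adjusted p = 9.61e-09), T cells 5 of 11 and 10 (1.34, adjusted p = 9.83e-05), neutrophils 6 of 10 and 9 (2.58, adjusted p = 0.002), macrophages and monocytes 4 of 10 and 6 (1.26, adjusted p = 0.009), and fibroblasts 8 of 10 and 9 (1.98, adjusted p = 0.000101). IL7R, the interleukin 7 receptor of T cells, was 2.44 ± 0.51 higher (adjusted p = 0.0144), and TNFRSF10C, a decoy receptor abundant on neutrophils, 2.63 higher. The collagen gene COL6A3 (chromosome 2, 238232646 to 238323018) stood at 1745 ± 1614 against 400 ± 133 CPM (2.13 ± 0.45, adjusted p = 0.0145). Adipocyte markers were lower in 3 of 6, all 6 adjusted over the list alone (-2.69, adjusted p = 2.26e-05). LIPE, the hormone-sensitive lipase (chromosome 19, 42905659 to 42931578), was at 11.3 ± 11 against 59.3 ± 36.1 CPM (-2.40 ± 0.56, adjusted p = 0.0174). Markers of melanocytes (-0.91, adjusted p = 0.001), eccrine and apocrine glands (-0.68, adjusted p = 0.002), smooth muscle (-0.50, adjusted p = 0.022) and skeletal muscle (-1.35, adjusted p = 0.007) were lower as lists. These calls, too, had adjusted p of 0.333 to 0.366 with an estimated correlation.

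Lists with no camera call were mast cells (0.81, adjusted p = 0.067), endothelium (0.32, adjusted p = 0.125), hair follicle (-2.77, adjusted p = 0.127) and sebaceous glands (-1.52, adjusted p = 0.176). Dendritic and Langerhans cells had a median of -0.26, a mean of 0.03 and a test pointing down (adjusted p = 0.122), with 1 member higher and 2 lower over all genes. The lower ones were the Langerhans cell genes CD1A (-1.34) and CD207 (-1.59 ± 0.49, adjusted p = 0.045), which lost their calls without nonlesional replicates 6 (adjusted p = 0.0537) and 4 (0.0865). Red blood cells had a median of 0.80 with a test pointing down (adjusted p = 0.614).

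Most genes with the largest increases rested on single libraries. ABCC11, a transporter of apocrine glands, was at 281 ± 832 against 1.59 ± 2.57 CPM (7.5 ± 2.02, adjusted p = 0.0275), and lesional replicate 7 held 98.8% of the lesional sum. Without that library its log2 fold change was 1.29 (adjusted p = 0.322). ACSM1 (7.5 ± 2.36), DHRS2 (7.48 ± 2.26), UGT2B11 (7.43 ± 2.23) and B3GAT1 (5.58 ± 1.49) likewise had 97.7 to 99.6% of the sum in lesional replicate 7, all without a call in its absence, where their values were -0.22, 0.52, 0.31 and 0.30. AKR1B15 kept its call without the same library (5.5 ± 1.28, and 2.03 with adjusted p = 0.02). The collagenase gene MMP13 was at 63.9 ± 145 against 0.985 ± 1.24 CPM (5.99 ± 1.51, adjusted p = 0.0222), and at 4.07 (adjusted p = 0.062) without lesional replicate 4. The largest decreases were mainly in genes of fat, PCK1 (-3.37 ± 0.88), the hormone leptin gene LEP (-3.36 ± 0.96), RBP4 (-3.01 ± 0.89), TRARG1 (-2.89 ± 0.87) and the lipid droplet gene PLIN4 (-2.78 ± 0.75), with the hair keratin KRT31 (-3.13 ± 0.97), SYT8 (-2.89 ± 0.60) and the muscle actin ACTA1 (-2.85 ± 0.82). The calls of PCK1 and SYT8 held without the nonlesional library with most counts (adjusted p 0.0469 without replicate 1 and 0.0322 without replicate 7). Those of the others ended, LEP without nonlesional replicate 3 (0.056), KRT31, RBP4 and TRARG1 without replicate 1 (0.0922, 0.0606 and 0.063), ACTA1 without replicate 5 (0.0693) and PLIN4 without replicate 7 (0.0553).

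In all, edgeR called 1835 of 18147 genes between lesional and nonlesional skin at baseline, 1276 higher and 559 lower. Of these calls 1453 differed by at least 2-fold. Among all genes tested 4911 had an unadjusted p under 0.05. The share of higher genes was 69.5%, against 48.8% of 6310 calls by limma voom with quality weights. Leaving out 1 library moved the count to 3239 (without lesional replicate 7), 3157 (lesional 8), 1152 (lesional 3), 1096 (lesional 2), 987 (lesional 6), 944 (lesional 4), 1194 (nonlesional 9), 1156 (nonlesional 8), 1038 (nonlesional 4) or 898 (nonlesional 7). Within title series no gene was called by edgeR, with 4897 genes at an unadjusted p under 0.05 among 6 against 6 samAx libraries and 2525 among 3 against 3 samX libraries.

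List scores, which give each library 1 value, differed for 6 of 29 lists by exact permutation, and for 0 with the median over members or among samAx libraries alone. B cells and plasma cells scored 5.43 ± 1.60 in lesional and 3.20 ± 0.86 in nonlesional skin (difference 2.24 ± 0.61 SE, n = 9 each, exact p = 0.003, adjusted p = 0.025). The cornified layer scored 8.08 ± 1.05 against 9.59 ± 0.67 (difference -1.51 ± 0.42, exact p = 0.002, adjusted p = 0.025) and adipocytes 3.12 ± 1.73 against 6.08 ± 1.58 (-2.96 ± 0.78, exact p = 0.003, adjusted p = 0.025). Type I interferon response (0.98 ± 0.35, exact p = 0.01, adjusted p = 0.047), melanocytes (-1.30 ± 0.45, exact p = 0.01, adjusted p = 0.047) and skeletal muscle (-0.49 ± 0.13, exact p = 0.003, adjusted p = 0.025) passed as well. The IL-17 response score was 4.47 ± 1.83 against 2.88 ± 0.75, a difference of 1.59 ± 0.66 that did not pass adjustment (exact p = 0.033, adjusted p = 0.073). It was 1.63 in the samAx and 1.51 in the samX libraries. The score differences of the 6 passing lists were, in samAx and then samX, 1.96 and 2.79 for B cells and plasma cells, -1.69 and -1.14 for the cornified layer, -2.32 and -4.25 for adipocytes, 0.81 and 1.33 for type I interferon response, -1.60 and -0.68 for melanocytes, and -0.53 and -0.40 for skeletal muscle. Of the 29 lists, 6 had score differences of opposite sign in the 2 series: hair follicle (0.17 and -3.67), sebaceous glands (0.12 and -2.68), IL-17 and IL-23 axis (-0.25 and 0.13), type 2 inflammation (-0.08 and 0.18), immediate early response (-0.50 and 0.28) and red blood cells (-0.61 and 0.27).

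Perilesional skin was compared with nonlesional skin to ask how far the tissue beside a lesion departs from uninvolved skin. By camera, lists of interferon, inflammatory and B cell genes were higher in perilesional skin and the cornified layer and adipocyte lists lower. None of the 23 camera calls held with an estimated correlation (adjusted p 0.272 to 0.484 with an estimated correlation). Fry, which tests each list on its own and not against other genes, called 15 of 29 lists (lowest adjusted p = 0.004). IFI6, an interferon-induced inhibitor of apoptosis (chromosome 1, 27992572 to 27998729), was at 86.5 ± 83.8 against 14.5 ± 5.55 CPM (SD, n = 9 each; log2 fold change 2.65 ± 0.49, adjusted p = 0.00956), and all 9 perilesional libraries lay above the nonlesional median. ICAM1, an adhesion molecule for leukocytes (chromosome 19, 10381511 to 10397291), was at 140 ± 82.6 against 44.3 ± 21.2 CPM (1.71 ± 0.35, adjusted p = 0.0107). LIPE, which had the lowest adjusted p of the adipocyte list, was at 6.83 ± 5.05 against 60.1 ± 37.3 CPM (-3.10 ± 0.48, adjusted p = 0.00502). TIMP1, an inhibitor of metalloproteinases (chromosome X, 47441712 to 47446188), was at 400 ± 200 against 137 ± 49.9 CPM (1.60 ± 0.32, adjusted p = 0.0107).

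Of the pathway lists in perilesional skin, the IL-17 response had 8 of 16 members higher and 12 adjusted over the list alone (2.94, camera adjusted p = 2.39e-06). Type I interferon response had 11 of 14 and 14 (1.73, adjusted p = 1.5e-07), interferon gamma response 7 of 11 and 9 (2.73, adjusted p = 0.000598), TNF, IL-1 and IL-6 inflammation 6 of 12 and 8 (2.03, adjusted p = 0.000504), complement 6 of 12 and 10 (1.21, adjusted p = 9.03e-06), matrix metalloproteinases and tissue remodelling 5 of 7 and 7 (4.06, adjusted p = 0.001), and epidermal activation 3 of 14 and 3 (1.39, adjusted p = 0.027). The cornified layer had 10 of 14 lower and 14 adjusted over the list alone (-1.36, adjusted p = 9.85e-10). KRT2, a keratin of the upper epidermis, was at a log2 fold change of -2.33 ± 0.54. All of these lists lost the call with an estimated correlation (adjusted p 0.272 to 0.484 over the 23 called lists). IL17RE, the receptor subunit for IL-17C, was lower at 32.8 ± 24.1 against 88.0 ± 28.5 CPM (-1.39 ± 0.34, adjusted p = 0.0153).

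Among cell types, B cells and plasma cells had 12 of 15 markers higher and 14 adjusted over the list alone (3.34, camera adjusted p = 1.98e-06), fibroblasts 8 of 10 and 9 (2, adjusted p = 5.92e-05), T cells 7 of 11 and 11 (1.43, adjusted p = 6.52e-05) and macrophages and monocytes 6 of 10 and 7 (1.60, adjusted p = 0.000504). All 6 adipocyte markers were lower, over all genes and adjusted over the list alone (-3.79, adjusted p = 9.47e-08), and 2 of 7 hair follicle markers, 5 adjusted over the list alone (-3.46, adjusted p = 0.008; score difference -0.36 in samAx and -5.14 in samX). Adjusted p with an estimated correlation lay between 0.272 and 0.484 for these lists. MS4A1 was at 13.2 ± 16.8 against 0.804 ± 0.849 CPM (4.12 ± 0.85, adjusted p = 0.0107). SELE, the endothelial adhesion molecule E-selectin, was at 30.3 ± 21.8 against 7.71 ± 3.32 CPM (2 ± 0.40, adjusted p = 0.0107).

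Several of the largest changes in perilesional skin came from 1 library. Perilesional replicate 8 held 97.7% of the sum of the macrophage chitinase gene CHIT1 (6.36 ± 1.95), 95.9% of SPP1, which encodes osteopontin (5.52 ± 1.71), and 90.1% of the gelatinase gene MMP9 (4.72 ± 1.27). Without it the log2 fold changes were 1.12, 1.07 and 1.58 and the calls ended (adjusted p 0.567, 0.546 and 0.165). HTRA4 went from 4.86 ± 1.02 to 3.24 and stayed called (0.0174). ABCC11 (6.14 ± 1.92) and B3GAT1 (4.55 ± 1.38) rested on perilesional replicate 7 (0.45 and -0.09 without it), MMP13 (4.61 ± 1.35) on replicate 4 (2.91, adjusted p = 0.122) and CSF3, the neutrophil growth factor gene, on replicate 6 (4.52 ± 1.39, and 3.35 with adjusted p = 0.103). The largest decreases that held without the top nonlesional library were in the fat genes TRARG1 (-4.27 ± 0.73), LEP (-4.17 ± 0.99), PLIN1 (-3.92 ± 0.89) and CIDEC (-3.82 ± 0.78), in the metabolic enzyme gene GLYAT (-3.81 ± 0.88) and in KRT31 (-3.80 ± 0.91). The hair keratin KRT86 (-5.05 ± 1.58) and GPRC5D (-4.84 ± 1.34) did not hold, KRT86 without nonlesional replicate 2 (adjusted p = 0.0831) and GPRC5D without nonlesional replicate 1 (0.053). Both had positive values among samAx libraries (1.95 and 0.46).

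In perilesional against nonlesional skin edgeR called 2391 of 18399 genes, 1567 higher, with 1796 at least 2-fold apart and 5219 at an unadjusted p under 0.05. Limma voom with quality weights called 5603 genes, with 54.3% higher against 65.5% by edgeR. The count was 3620 without perilesional replicate 7, 1402 without nonlesional replicate 7, 1475 without nonlesional replicate 4 and 1500 without perilesional replicate 4. Among samAx libraries (6 against 6) it was 2878, of which 1440 were among the 2391. With samX libraries (3 against 3) it was 0 by edgeR, with 3249 genes at an unadjusted p under 0.05. Scores passed for 16 of 29 lists, 12 with the median over members and 0 among samAx libraries alone, including the IL-17 response (4.44 ± 1.21 against 2.88 ± 0.75, n = 9 each, exact p = 0.006, adjusted p = 0.025; 1.37 in samAx and 1.93 in samX) and adipocytes (2.51 ± 1.29 against 6.08 ± 1.58, exact p = 0.000411, adjusted p = 0.012; -3.24 in samAx and -4.26 in samX).

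**Figure D2:**
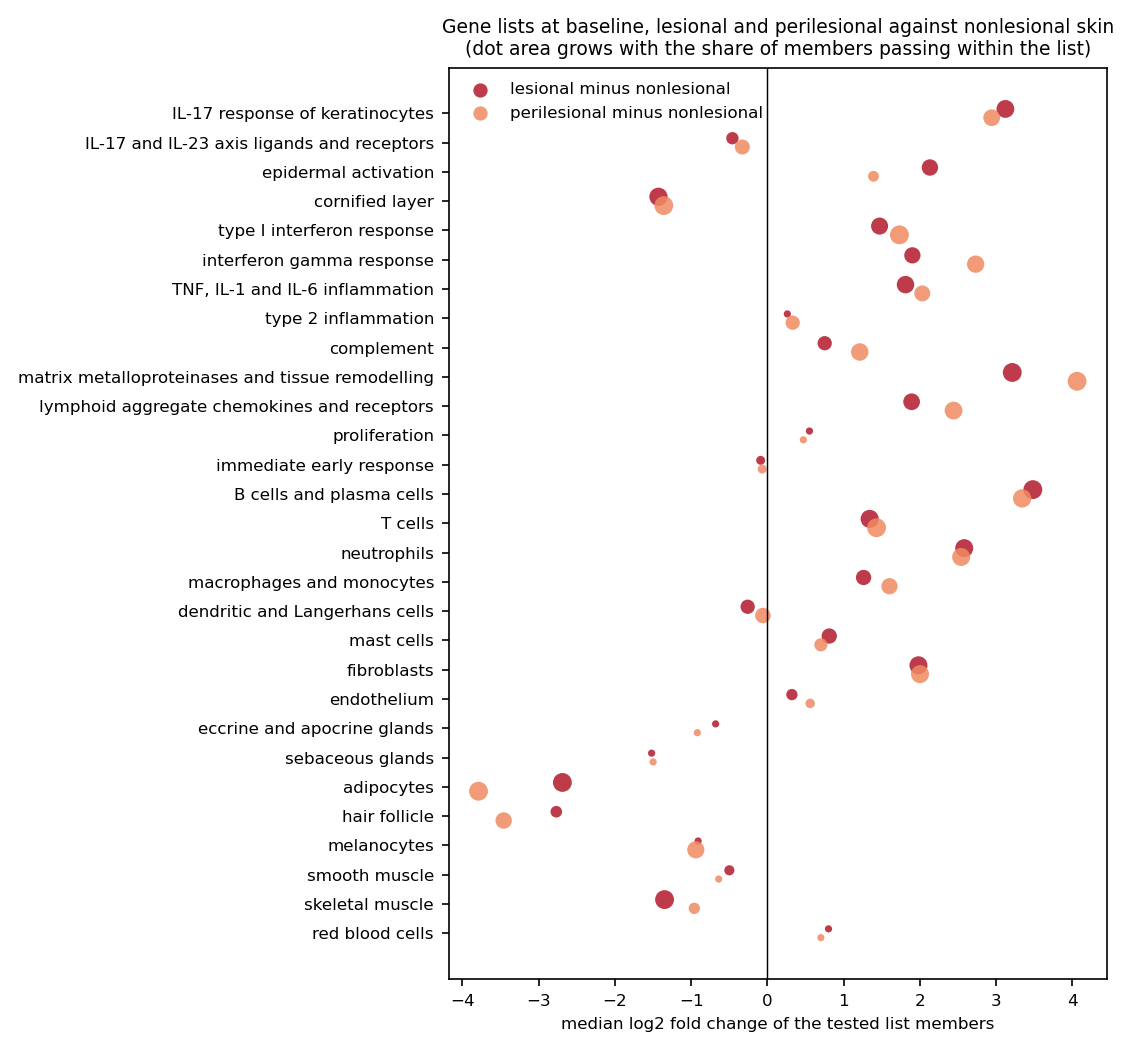
Median log2 fold change of the tested members of each of the 29 gene lists on the horizontal axis, lists on the vertical axis, for lesional (dark red) and perilesional (orange) against nonlesional skin at baseline, with dot area growing with the share of members passing within the list. Matrix metalloproteinase and B cell lists lay farthest right (3.21 and 3.48 in lesional skin) and adipocytes far left (-2.69 and -3.79).

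The 2 baseline comparisons called many of the same genes. Of 18042 genes tested in both, 1270 were higher in lesional and 1532 in perilesional skin, 1045 of them in both, where independent lists would share 107.8. Lower were 559 and 821, with 392 in both against 25.4, and 0 genes were called in opposite directions. The comparisons share the nonlesional libraries. With unchanged groups simulated against shared controls 0 genes were called in both. With the nonlesional libraries split between the comparisons the median number of calls over 10 draws was 0. Unchanged groups hold no changes to call and the split fits called too few, so neither value shows how far shared controls raise the overlap. Lesional and perilesional libraries of a title set also deviated together (median r 0.61, other pairs -0.11). The expectation for independent lists does not take this in. Across 16053 genes, which are not independent, the log2 fold changes correlated with Pearson r = 0.934 (covariance 0.562). The simulated value for unchanged groups with shared controls was 0.462 (covariance 0.077), and the value with split controls was 0.763 (covariance 0.501).

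Set against each other, lesional and perilesional skin at baseline showed no gene past the threshold. The IL-17 response score was 4.47 ± 1.83 against 4.44 ± 1.21 (n = 9 each), a difference of 0.03 with a 95% interval from -1.53 to 1.6. This interval treats the libraries as independent, although lesional and perilesional libraries of a title set deviated together (median r 0.61). Differences inside this unpaired interval were not excluded, and no paired interval was computed at baseline. KRT6A, a keratin of wounded epidermis, was at 3445 ± 3712 against 1730 ± 1469 CPM (1.01 ± 0.78, adjusted p = 1), and MMP9 at 101 ± 119 against 671 ± 1785 CPM (-2.70 ± 1.23, adjusted p = 1). Most of the perilesional MMP9 sum came from perilesional replicate 8, as given above, so the direction of the MMP9 difference rests on that library. As lists, epidermal activation (median 0.70, camera adjusted p = 0.004) and B cells and plasma cells (0.25, adjusted p = 0.008) were higher in lesional skin, and complement (-0.37, adjusted p = 0.002), endothelium (-0.33, adjusted p = 0.004), macrophages and monocytes (-0.46, adjusted p = 0.006) and type I interferon response (-0.19, adjusted p = 0.012) lower. With an estimated correlation the lowest adjusted p was 0.464, for endothelium. The score differences turned between samAx and samX libraries for epidermal activation (1.23 and -0.78), type I interferon response (-0.61 and 0.38), macrophages and monocytes (-0.64 and 0.15) and the IL-17 response (0.26 and -0.42). They kept their sign for B cells and plasma cells (0.39 and 0.52), complement (-0.42 and -0.08) and endothelium (-0.23 and -0.44). Melanocytes were called down (adjusted p = 0.023) with a median of 0.01 and a mean of -0.04 (adjusted p = 0.728 with an estimated correlation). No gene was called by edgeR (0, with 57 at an unadjusted p under 0.05), DESeq2 (0, 141) or limma voom with quality weights (0, 348). No score passed (all adjusted p 0.996).

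The drug's target and the ligands of its receptor were examined at baseline and week 12, the tests of the ligands being added after the data were seen. IL17RA, the receptor subunit bound by brodalumab (chromosome 22, 17565844 to 17596583), was at 61.0 ± 12.4 CPM in lesional, 57.0 ± 13.2 in nonlesional (0.11 ± 0.16, adjusted p = 0.687) and 70.5 ± 26.0 CPM in perilesional skin (0.35 ± 0.21 against nonlesional, adjusted p = 0.284). At week 12 against baseline its log2 fold change was 0.03 ± 0.16 in lesional, -0.42 ± 0.20 in perilesional (adjusted p = 1) and -0.14 ± 0.15 in nonlesional skin. IL17A (chromosome 6, 52051185 to 52055436) was at 1.40 ± 2.01 CPM in lesional, 0.88 ± 1.17 in perilesional and 0.0758 ± 0.0885 CPM in nonlesional skin at baseline. Here 6 of 9 lesional libraries lay above the highest nonlesional one (n = 9 each, exact p = 0.0118, adjusted p = 0.0896 over 27 tests). At week 12 IL17A was at 0.694 ± 0.623 CPM in lesional skin (against baseline, n = 9 each, exact p = 0.509) and 0.474 ± 0.446 in perilesional skin (exact p = 0.51). IL17F (chromosome 6, 52101479 to 52109335) went from 1.24 ± 1.87 to 0.676 ± 0.674 CPM in lesional skin (n = 9 each, exact p = 0.583) and from 1.5 ± 1.94 to 0.527 ± 0.653 CPM in perilesional skin (exact p = 0.249). IL17C (chromosome 16, 88704999 to 88706881) was at 0.202 ± 0.271 CPM in lesional skin at baseline and 0.229 ± 0.127 CPM at week 12. None of the 27 tests of these ligands passed adjustment, the lowest adjusted p being 0.0896.

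Week 12 was compared with baseline in lesional skin to ask what changed in lesions under treatment. The IL-17 response score was 4.55 ± 1.47 at week 12 and 4.47 ± 1.83 at baseline (n = 9 each; difference 0.08 ± 0.78, exact p = 0.919, 95% interval -1.59 to 1.77). Proliferation genes were higher as a list (median 0.85, camera adjusted p = 7.74e-09; adjusted p = 0.489 with an estimated correlation), with 0 of 10 members past the threshold and 1 adjusted over the list alone. MKI67, a marker of dividing cells (chromosome 10, 129894923 to 129924649), was at 42.9 ± 26.1 against 23.0 ± 13 CPM (0.89 ± 0.36, adjusted p = 0.987). Fibroblast markers were lower as a list (-0.54, adjusted p = 0.03; adjusted p = 0.988 with an estimated correlation), COL3A1 being at 8101 ± 11083 against 14680 ± 18420 CPM (-0.84 ± 0.78, adjusted p = 0.987).

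Single genes of other groups in lesional skin did not pass the threshold at week 12. S100A9, a neutrophil and keratinocyte alarmin, was at 3913 ± 3974 against 2512 ± 2740 CPM (0.61 ± 0.94), KRT1 at 14118 ± 12163 against 9934 ± 6345 CPM (0.49 ± 0.71), SOCS3 at 105 ± 79.3 against 111 ± 111 CPM (-0.08 ± 0.64), and the haemoglobin gene HBB at 96.2 ± 91.9 against 564 ± 884 CPM (-2.58 ± 0.99), all with an adjusted p of 0.987 or above. Between week 12 and baseline in lesional skin edgeR called 0 genes, with 401 at an unadjusted p under 0.05, limma voom with quality weights called 0 (1346) and DESeq2 1 (649). Without lesional week 12 replicate 2, which held little epidermal RNA, edgeR again called 0 genes and 1094 had an unadjusted p under 0.05. The score of proliferation differed by 0.65 ± 0.33 (n = 9 each, exact p = 0.066, adjusted p = 0.99; 0.70 among the samAx libraries), and that of the IL-17 response by -0.08 among samAx libraries. All week 12 libraries are samAx, so 9 were compared with 6.

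In perilesional skin at week 12, interferon and inflammatory lists were lower by camera than at baseline and epidermal activation and proliferation higher, all with adjusted p = 0.836 with an estimated correlation. The IL-17 response score was 4.44 ± 1.24 against 4.44 ± 1.21 (n = 9 each; difference 0.00 ± 0.58, 95% interval -1.23 to 1.23). Type I interferon response (median -0.80, camera adjusted p = 3.66e-05), endothelium (-0.46, adjusted p = 7.69e-05), TNF, IL-1 and IL-6 inflammation (-0.71, adjusted p = 0.003), complement (-0.39, adjusted p = 0.003), macrophages and monocytes (-0.55, adjusted p = 0.006), smooth muscle (-0.62, adjusted p = 0.007), interferon gamma response (-1.24, adjusted p = 0.014) and T cells (-0.66, adjusted p = 0.022) were lower. Proliferation (0.35, adjusted p = 0.007) and epidermal activation (1.03, adjusted p = 0.014) were higher. All 10 had an adjusted p of 0.836 with an estimated correlation, and no member of any list passed over all genes. ICAM1 was at 85.9 ± 73.9 against 141 ± 83.2 CPM (-0.71 ± 0.51, adjusted p = 1) and KRT6A at 5063 ± 6702 against 1720 ± 1451 CPM (1.49 ± 0.88, adjusted p = 1). In perilesional skin edgeR called 0 genes (481 at an unadjusted p under 0.05), as did DESeq2 (684) and limma voom with quality weights (1140). The lowest unadjusted p of a score was that of endothelium (-0.57 ± 0.27, n = 9 each, exact p = 0.045, adjusted p = 0.959). Among samAx libraries the score differences were -0.80 for type I interferon response and -0.72 for TNF, IL-1 and IL-6 inflammation.

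In nonlesional skin, adipocyte markers were lower at week 12 than at baseline and other lists moved less. The adipocyte score was 3.48 ± 1.72 against 6.08 ± 1.58 (n = 9 each; difference -2.61 ± 0.78, exact p = 0.005, adjusted p = 0.15, 95% interval -4.26 to -0.95; -2.20 among samAx libraries), and the list was lower by camera (median -2.12, adjusted p = 1.46e-09; adjusted p = 0.28 with an estimated correlation). None of its 6 members passed over all genes, and all 6 passed adjusted over the list alone; PLIN4 was at 74.5 ± 75.7 against 485 ± 309 CPM (-2.71 ± 0.66, adjusted p = 0.624). Melanocyte markers were lower (-0.65, adjusted p = 0.002; adjusted p = 0.596 with an estimated correlation). IL-17 response genes were higher as a list (0.93, camera adjusted p = 0.004, and 0.91 with an estimated correlation), with a score of 3.35 ± 0.85 against 2.88 ± 0.75 (n = 9 each, exact p = 0.24). Week 12 replicate 1 stood apart at 5.27 (the others 2.25 to 3.82), and at 8.37 for epidermal activation (the others 4.15 to 6.96). Epidermal activation (0.55, adjusted p = 0.04) and lymphoid aggregate genes (0.69, adjusted p = 0.028) were called up as well, and both calls ended without nonlesional week 12 replicate 9, in which few genes were detected. The cornified layer (down, adjusted p = 0.004) and eccrine and apocrine glands (up, adjusted p = 0.017) were gained, both with adjusted p = 0.918 with an estimated correlation. With an estimated correlation the adjusted p of the 5 called lists lay between 0.28 and 0.91. In nonlesional skin edgeR called 0 genes (1326 at an unadjusted p under 0.05), limma voom with quality weights 0 (2651) and DESeq2 13 (1614).

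**Figure D3:**
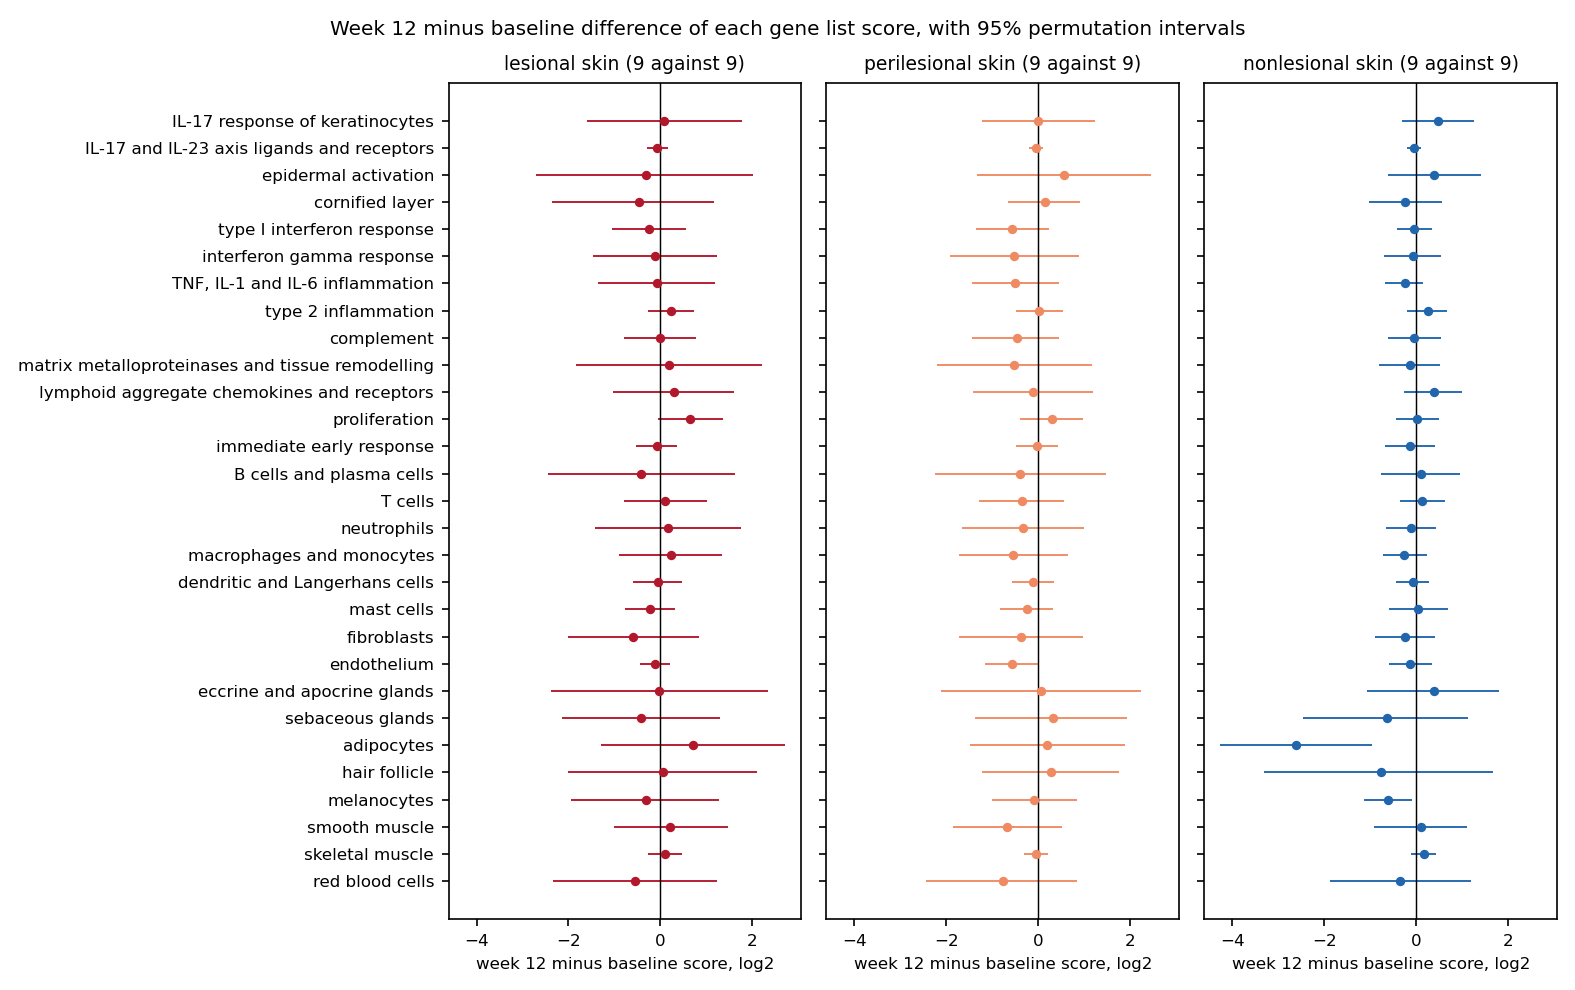
Week 12 minus baseline difference of each list score (log2 units, horizontal axis) for the 29 gene lists (vertical axis), with 1 panel each for lesional, perilesional and nonlesional skin, 9 against 9 libraries, and bars giving 95% permutation intervals. The IL-17 response differed by 0.08, 0.00 and 0.47, and the adipocyte interval in nonlesional skin ran from -4.26 to -0.95.

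Whether the week 12 change differed between sites was tested directly. Adipocyte markers changed differently in lesional and nonlesional skin (median difference of log2 fold changes 3.62, camera adjusted p = 1.21e-14; adjusted p = 0.03 with an estimated correlation), with 5 of 6 members adjusted over the list alone and 0 over all genes. Without lesional week 12 replicate 2 and nonlesional week 12 replicate 9 the median was 3.54, and adjusted p = 0.523 with an estimated correlation. In perilesional against nonlesional skin the adipocyte difference was 3.55 (camera adjusted p = 6.26e-09, and 0.223 with an estimated correlation). That of the IL-17 response was -0.73 (camera adjusted p = 0.015, and 0.61 with an estimated correlation). It includes nonlesional week 12 replicate 1, whose IL-17 response score of 5.27 stood apart from the others. Over single genes edgeR called 0 in the lesional and 0 in the perilesional contrast, with 458 and 540 at an unadjusted p under 0.05, and DESeq2 0 (455) and 1 (614).

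At week 12, lesional skin differed from nonlesional skin in 18 lists by camera, 0 of them with an estimated correlation (adjusted p 0.229 to 0.341 with an estimated correlation), and in 0 lists by fry (lowest adjusted p = 0.059). B cells and plasma cells had 14 of 15 markers higher adjusted over the list alone and 0 over all genes (median 3.94, camera adjusted p = 3.73e-06), neutrophils 9 and 0 (3.04), TNF, IL-1 and IL-6 inflammation 8 and 0 (1.81, adjusted p = 9.42e-07), type I interferon response 7 and 0 (0.77, adjusted p = 2.71e-08) and the IL-17 response 6 and 0 of 16 (2.15, adjusted p = 0.000326). The cornified layer (-0.91, adjusted p = 2.86e-06) and eccrine and apocrine glands (-1.37, adjusted p = 3.32e-05) were lower. The IL-17 response score was 4.55 ± 1.47 against 3.35 ± 0.85 (n = 9 each; difference 1.20 ± 0.56, exact p = 0.051, adjusted p = 0.115), and no score passed (lowest adjusted p = 0.064). EdgeR called 0 genes, with 2383 at an unadjusted p under 0.05, while DESeq2 called 839, limma voom with quality weights 777 and edgeR with all 75 libraries in 1 fit 304. Without lesional replicate 2 and nonlesional replicate 9 the epidermal activation list, at a median of 1.44 (adjusted p = 0.204) with all libraries, was called up (adjusted p = 2.06e-08; adjusted p = 0.214 with an estimated correlation), and the melanocyte call ended.

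Perilesional skin at week 12 differed from nonlesional skin by higher type I interferon response (median 0.73, camera adjusted p = 5.91e-10), fibroblast (1.76, adjusted p = 5.67e-06), IL-17 response (2.04, adjusted p = 4.76e-05) and B cell lists (3.49, adjusted p = 0.000286), and lower cornified layer (-1.27, adjusted p = 1.42e-09), gland (-1.43, adjusted p = 1.71e-08), smooth muscle (-1.53, adjusted p = 4.57e-07) and skeletal muscle lists (-2.29, adjusted p = 0.00097). With an estimated correlation the adjusted p of the 21 called lists lay between 0.064 and 0.422. Fry called 2 lists (lowest adjusted p = 0.013). The scores of type I interferon response (0.73 ± 0.20, n = 9 each, exact p = 0.004, adjusted p = 0.036), smooth muscle (-1.79 ± 0.52, exact p = 0.003, adjusted p = 0.036) and skeletal muscle (-0.60 ± 0.13, exact p = 0.000576, adjusted p = 0.017) passed, and that of the IL-17 response did not (1.09 ± 0.50, exact p = 0.048, adjusted p = 0.14). Without nonlesional week 12 replicate 9, in which few genes were detected, type I interferon response no longer passed (0.68, n = 9 and 8, exact p = 0.007, adjusted p = 0.052) and eccrine and apocrine glands did (-3.27, exact p = 0.004, adjusted p = 0.042). With the median over members 0 scores passed, and with RLE size factors only skeletal muscle. EdgeR called 0 genes (2503 at an unadjusted p under 0.05), DESeq2 620 and limma voom with quality weights 93.

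Lesional and perilesional skin at week 12 differed by 0.12 in the IL-17 response score (95% interval -1.25 to 1.48). With the 9 title sets as pairs, a test added after the data were seen, its interval ran from -0.55 to 0.8 (n = 9 pairs, 5 higher in lesional skin, exact sign-flip p = 0.723, adjusted p = 0.838). No paired score passed, the lowest adjusted p being 0.481, as for T cells (0.45 ± 0.18, higher in 8 of 9 pairs, exact p = 0.023). With 512 sign flips a list on its own could not pass adjustment over 29 lists, however large its difference. T cell (0.48, camera adjusted p = 1.88e-06), neutrophil (0.75, adjusted p = 1.88e-06), TNF, IL-1 and IL-6 inflammation (0.58, adjusted p = 3.7e-06), smooth muscle (0.85, adjusted p = 1.51e-05), proliferation (0.43, adjusted p = 1.54e-05) and adipocyte lists (1.04, adjusted p = 0.000193) were higher in lesional skin; the lowest adjusted p was 0.465 with an estimated correlation. The cornified layer was called down (adjusted p = 6.12e-05) with a median of 0.08 and a mean of 0.10, and this call ended without lesional replicate 2 (adjusted p = 0.915). Without that library camera called 13 lists against 15. It also lost interferon gamma response (0.224), matrix metalloproteinases and tissue remodelling (0.284), macrophages and monocytes (0.229) and melanocytes (0.985). Gained were epidermal activation (up, 0.008), fibroblasts (down, 0.000403) and eccrine and apocrine glands (up, 0.017), with adjusted p of 0.624 to 0.74 with an estimated correlation, and 116 genes had an unadjusted p under 0.05. EdgeR called 0 genes (72 at an unadjusted p under 0.05), as did DESeq2 (152), limma voom with quality weights (292) and the replicate block (339). With the block, camera called 16 lists against 15; melanocytes were lost (adjusted p = 0.003 to 0.05), and fibroblasts (down, adjusted p = 0.016, from 0.225) and eccrine and apocrine glands (up, adjusted p = 0.000873, from 0.067) were gained, with 0 calls at an estimated correlation.

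At week 4, with 4 libraries per site against 9, camera called 17 lists in nonlesional, 1 in perilesional and 0 in lesional skin. Whether the sites differed was not tested. In nonlesional skin adipocyte markers (median -1.14, camera adjusted p = 4.56e-10) and the cornified layer (-0.54, adjusted p = 4.8e-05) were lower, and epidermal activation (1.31, adjusted p = 1.01e-05), red blood cells (3.45, adjusted p = 0.000358) and the IL-17 response (0.92, adjusted p = 0.002) higher, with adjusted p of 0.235 to 0.657 over the 17 called lists with an estimated correlation. Nonlesional week 4 replicate 3 scored 5.15 for the IL-17 response (the others 2.67 to 2.78, baseline mean 2.88) and 8.47 for epidermal activation (the others 5.52 to 5.67, baseline mean 5.61). Replicate 4 scored 9.58 for red blood cells (the others 3.47 to 4.86, baseline mean 4.20). Hair follicle markers were called up (adjusted p = 0.041) with a median of -2.73 and a mean of -2.71. Camera used log2 CPM from voom, while the median and mean are of edgeR log2 fold changes, so their signs can differ. The hair follicle scores at week 4 ran from 2.83 to 4.32. The baseline mean was 3.61, with 8.36 and 7.97 in baseline replicates 1 and 2. Neither an increase nor a decrease can be read from these values. The list called in perilesional skin was skeletal muscle (adjusted p = 0.478 with an estimated correlation). No score passed in the 3 sites. EdgeR called 0 genes in lesional, perilesional and nonlesional skin, with 3181, 707 and 204 at an unadjusted p under 0.05, and DESeq2 called 326, 1 and 0. Without lesional week 4 replicate 4 and perilesional week 4 replicate 4, in which few genes were detected, the unadjusted numbers were 1468 and 181. Leaving out 1 other library moved the perilesional number to 1684, 1245 or 1092 (week 4 replicates 1, 2 and 3), 436, 444 or 1318 (baseline replicates 3, 4 and 6), and the nonlesional number to 398 or 473 (week 4 replicates 2 and 4) or 353 (baseline replicate 6).

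At week 2, with 2 libraries per site, cornified layer genes were lower in lesional skin (-1.56, camera adjusted p = 2.36e-11; adjusted p = 0.53 with an estimated correlation), where replicate 2 held little epidermal RNA, and T cell genes were higher (1.12, adjusted p = 3.9e-05; adjusted p of 0.53 to 0.781 with an estimated correlation over the 10 called lists). The T cell score was 3.77 in replicate 1 and 5.77 in replicate 2, which had 37.17% immunoglobulin counts, with a baseline mean of 3.76. In perilesional skin adipocyte markers were higher (2.02, adjusted p = 1.62e-12; adjusted p = 0.183 with an estimated correlation), and in nonlesional skin gland (-2.23, adjusted p = 5.95e-06; adjusted p = 0.543 with an estimated correlation) and proliferation genes (-0.63, adjusted p = 0.000299; adjusted p = 0.878 with an estimated correlation) lower. Gland scores in nonlesional skin were 4.75 and 1.49 in the 2 libraries (baseline mean 5.34) and proliferation scores 2 and 3.04 (baseline mean 3.15). EdgeR called 0 genes in each site, with 353, 364 and 1329 at an unadjusted p under 0.05 in lesional, perilesional and nonlesional skin. DESeq2 called 0, 1 and 53, and limma voom with quality weights 0 in each. All week 2 libraries are samX; against the 3 samX baseline libraries of each site edgeR called 0 genes too, with 66, 272 and 1434 at an unadjusted p under 0.05. Without lesional week 2 replicate 1, edgeR called 18 genes in lesional skin (2916 unadjusted). That fit held 1 week 2 library, replicate 2 with little epidermal RNA. In each fit that left out a week 2 library, the remaining one was assumed to vary like the baseline libraries. The unadjusted number there was 171 without week 2 replicate 2 and 541 without baseline replicate 2, and in nonlesional skin 809 and 2488 without week 2 replicates 1 and 2.

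The baseline difference between lesional and nonlesional skin was set against the week 12 change in lesional skin across 16053 genes, which are not independent. Pearson r was -0.267 (covariance -0.077). Unchanged groups that share the baseline lesional libraries gave -0.465 (covariance -0.096; range -0.838 to 0.164 over 100 simulations). With the baseline lesional libraries split between the comparisons r was -0.007 (covariance 0.023; range -0.397 to 0.553 over 100 draws).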

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

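The tests of the deep glands and of the title series for the adipocyte pattern, of depth for the library with little epidermal RNA, of immunoglobulin in swapped labels, and of lists without the libraries with few genes or little epidermis, were chosen only after the results they measure were seen. A library was singled out when it lay far from the others of its group relative to the group's range, a list when its week 12 change differed between sites by camera, and week 8 when a lesional score lay above the highest nonlesional baseline score. Of 297 groups and measures examined for a library far from the rest, 21 met the criterion, in 15 libraries; chance alone does so in about 1 in 20 groups.

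The first pattern was the lower level of adipocyte markers in nonlesional skin at week 12 than at baseline. Less fat tissue in the week 12 biopsies fits: 10 further adipocyte genes, outside the fixed lists, had a median log2 fold change of -1.56 (SE 0.23 over genes), and all 10 were lower. That SE treats the genes as independent and does not measure the spread between libraries. Taken singly, none passed by edgeR over all genes (adjusted p 0.624 to 0.77). These genes were measured in the same libraries and would also be lower if fat cells expressed less. They cannot tell the amount of fat from its expression. Shallower biopsies would hold fewer deep glands too, and stay open, the gland score differing by 0.39 (SE 0.68). A difference between the 2 series of library titles was excluded as the whole cause, since among samAx libraries alone the score differed by -2.20 (SE 0.92), over 2 SE from 0, against -2.61 in all; a part in it stays open. An effect of treatment on fat stays open as untested, because the design holds no untreated skin at week 12.

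The second pattern was lesional week 12 replicate 2, which held little epidermal RNA, with an epidermal activation score of 0.75 and a cornified layer score of 1.59. Tissue without epidermis fits: 12 further epidermal genes lay a median of 7.81 log2 units under the other 8 libraries (difference -7.81, SE 0.47 over genes, not over libraries). A few genes taking most of the counts was excluded, since the cornified layer score was 1.85 with immunoglobulin and the 10 most abundant genes left out of the totals, and the lowest of the others was 7.29. Low depth was excluded, at 39.65 M counts with 31.58 M as the lowest of the others. No biological explanation was tested.

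The third pattern was the spread of the IL-17 response score in lesional skin at baseline, from 2.09 to 6.59, with 5 of 9 libraries at or below the highest nonlesional score of 4.17. A difference between the 2 series of library titles was excluded as the whole cause, since the 5 held 2 of 3 samX and 3 of 6 samAx libraries. A part in it stays open. A swap of lesional and nonlesional labels was excluded for all 5 together, since 3 of them had immunoglobulin shares of 2.82, 7.24 and 17.26% against a nonlesional maximum of 1.17%, but stays open for some, with 1 nonlesional library above the lesional median and 2 lesional libraries below the nonlesional median. Low depth stays open too, at Pearson r = -0.06 with the total count (n = 9, exact p = 0.88). That lesions differ in activity between patients stays open as untested.

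The following libraries lay far from their groups. In lesional skin, baseline replicate 7 had 22.15% mitochondrial counts, week 4 replicate 3 an epidermal activation score of 9.20 and week 12 replicate 8 a smooth muscle score of 7.49. In perilesional skin, baseline replicate 7 had an eccrine and apocrine gland score of 7.87 and a sebaceous gland score of 7, replicate 8 a hair follicle score of 5 and replicate 6 a melanocyte score of 3.28. Week 4 replicate 3 had an interferon gamma response score of 7.13, and week 12 replicate 4 had 36.78% immunoglobulin counts. In nonlesional skin at baseline, replicate 6 had an interferon gamma response score of 5 and a type 2 inflammation score of 2.61, replicate 3 a proliferation score of 3.94 and replicate 5 a melanocyte score of 4.99. Nonlesional week 4 replicate 3 had scores of 5.15 for the IL-17 response, 8.47 for epidermal activation and 5.87 for interferon gamma response. Nonlesional week 12 replicate 1 had scores of 4.54 for proliferation and 1.32 for B cells and plasma cells, and replicate 2 a macrophage and monocyte score of 4.77.

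The week 12 change differed between lesional and nonlesional skin, by camera, for adipocytes (median difference of log2 fold changes 3.62, adjusted p = 0.03 with an estimated correlation), macrophages and monocytes (0.77), proliferation (0.66), B cells and plasma cells (0.46, with a mean of 0.19 and a test pointing down) and epidermal activation (-0.45). Between perilesional and nonlesional skin it differed for adipocytes (3.55), sebaceous glands (1.51), melanocytes (0.62), proliferation (0.29), cornified layer (0.17), B cells and plasma cells (-0.12), endothelium (-0.51), complement (-0.67), IL-17 response (-0.73), smooth muscle (-0.77), lymphoid aggregate genes (-0.77), interferon gamma response (-0.81), type I interferon response (-0.90) and T cells (-1). With an estimated correlation only the first of these 19 differences passed, and it did not (adjusted p = 0.523 with an estimated correlation) without lesional week 12 replicate 2 and nonlesional week 12 replicate 9. Without both, the lesional contrast also lost the camera calls of macrophages and monocytes (adjusted p = 0.491), B cells and plasma cells (0.521) and epidermal activation (0.521), and gained the cornified layer (0.001), fibroblasts (0.001), melanocytes (0.002) and hair follicle (0.029). Without nonlesional week 12 replicate 9 the perilesional contrast lost sebaceous glands (0.06) and B cells and plasma cells (0.127). None of these calls passed with an estimated correlation (adjusted p 0.402 to 0.98 with an estimated correlation).

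The single lesional library at week 8, which no comparison used, scored above the highest nonlesional baseline library for the IL-17 response (5.67 against 4.17), epidermal activation (7.74 against 7), type I interferon response (4.73 against 4.46), TNF, IL-1 and IL-6 inflammation (4.19 against 2.73), complement (7.48 against 6.92), matrix metalloproteinases and tissue remodelling (6.38 against 4.11), B cells and plasma cells (5.91 against 4.51), T cells (4.41 against 3.77), neutrophils (4.87 against 3.43), macrophages and monocytes (6.02 against 4.12) and fibroblasts (10.77 against 9.48).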

How the results depend on the processing

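The fits without few-gene or little-epidermis libraries, the leave-one-out fits at baseline and the paired list scores at week 12 were chosen only after the results were seen. Of 238 alternative counts, leave-one-out aside, 195 stayed within 1.5 times the main count and 43 did not. A count of 0 under both settings was taken as staying, which for some was fixed beforehand, such as a fold of at least 2 among 0 calls. Of the gene counts above 0, 6 of 11 stayed for baseline lesional against nonlesional skin and 8 of 11 for perilesional against nonlesional skin. The cause of the moves was not tested unless stated. Between lesional and nonlesional skin at baseline (1835 calls) DESeq2 called 3049 genes, limma voom with quality weights 6310 and all 75 libraries in 1 fit 764; samAx libraries alone gave 0 and samX libraries alone 0, with fewer libraries. Between perilesional and nonlesional skin (2391) voom called 5603, all 75 libraries 483 and samX alone 0. Leave-one-out counts ran from 898 to 3239 and from 1402 to 3620, and at week 2 in lesional skin from 0 to 18, with 1 week 2 library left, assumed to vary like the baseline ones, where 18 were called; at week 4 and elsewhere at week 2 all were 0.

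Where edgeR called 0, DESeq2 called 839 (week 12 lesional against nonlesional), 620 (perilesional against nonlesional), 326 (week 4 lesional), 53 (week 2 nonlesional), 13 (week 12 against baseline in nonlesional skin), and 1 each for week 12 against baseline in lesional skin, week 4 and week 2 in perilesional skin and the perilesional contrast of changes. Voom called 777 and 93 at week 12 in lesional and perilesional against nonlesional skin, all 75 libraries 304 at week 12 in lesional against nonlesional and 68 at week 4 in perilesional skin, and the replicate block 11 at week 12 in perilesional against nonlesional skin.

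With an estimated correlation the set tests called 0 lists in each comparison except the lesional contrast of changes, which kept 1. Scores at baseline called 0 of 6 lists in lesional skin with the median over members and 0 with samAx libraries alone, and 0 of 16 in perilesional skin with samAx alone. Among 6 against 6 samAx libraries a list on its own could not pass adjustment, so these samAx counts of 0 show little. At week 12 in perilesional skin they called 0 of 3 with the median over members and 1 with RLE size factors.

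Of 77 called named genes in lesional skin, RLE kept 77, DESeq2 73, voom 69, a mean CPM of at least 1 all 76 tested, the prefix as a covariate 66, the block 65, no filter 37, all 75 libraries 25, samAx alone 0 of 76 and samX alone 0 of 75. Of 84 in perilesional skin, RLE kept 84, a mean CPM of at least 1 83, DESeq2 74, voom 73, the prefix as a covariate 72, the block 66, no filter 63, samAx alone 53, all 75 libraries 30 and samX alone 0 of 82. Reversed in lesional skin were ACSM1 (voom -1.45) and UGT2B11 (voom -1.15). Reversed in perilesional skin were ABCC11 (voom -0.64), B3GAT1 (DESeq2 -0.10, voom -0.13), KRT86 (prefix as a covariate 0.15, samAx 1.95), GPRC5D (samAx 0.46) and PMEL (samX 0.06). The correlation of baseline difference with week 12 change went from -0.267 to -0.007 with split libraries (range -0.397 to 0.553 over draws), by construction without shared ones.

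Pairing by replicate block of 3 consecutive titles did not hold by its check at baseline or for nonlesional skin at week 12, where not all 9 pairs correlated above 0.1. At baseline 7 of 9 pairs correlated over 0.1 for lesional against nonlesional skin (median 0.45, other pairs -0.04). For perilesional against nonlesional skin 6 did (0.24, other pairs -0.06), and for lesional against perilesional skin 8 (0.61, other pairs -0.11). At week 12, against nonlesional skin, 6 did for lesional (0.40, other pairs -0.08) and 8 for perilesional skin (0.49, other pairs -0.06). Most sets thus deviated together there too, which the main tests, treating the libraries as independent, do not take in. Apart from the 11 genes above, the block moved no other total of calls by over 1.5 times. Between lesional and nonlesional skin at baseline, however, its 2613 calls held 1298 lower genes against 559 without it, and 50.3% were higher against 69.5%. For week 12 lesional against perilesional skin, where the pairing held, exact sign flips within sets passed 0 list scores. They could not have passed a list on its own, so this count adds little to the 0 without pairing. Not run were samX-only fits at week 4 (1 such library per site), samAx-only fits at week 2 (0 such libraries), and the samAx-only and title prefix alternatives between sites at week 12, where all libraries are samAx. The 1 to 4 libraries per site at weeks 2 to 8 limit what could pass. Whether the depth of the smallest library, 10.86 M counts, did so was not tested.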

Other observations

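The splits within title sets were chosen only after the results were seen; the other splits were planned beforehand. Scores at the times with few libraries are given as values. The IL-17 response score in lesional skin was 5.23 ± 0.25 at week 2 (n = 2), 3.87 ± 1.47 at week 4 (n = 4) and 5.67 at week 8 (n = 1); in perilesional skin 5.31 ± 0.20, 3.91 ± 2.31 and 3.47; and in nonlesional skin 3.70 ± 0.06, 3.33 ± 1.21 and 1.98. The adipocyte score in nonlesional skin was 7.24 ± 0.59 at week 2, 3.77 ± 2.51 at week 4 and 7.06 at week 8.

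The libraries of the 14 comparisons with at least 3 libraries per group were divided into 2 groups in 100 ways, the real one included, and the genes recounted; the week 2 comparisons (2 libraries per site) were not split. Between lesional and nonlesional skin at baseline 1 split, the real one, reached 1835 calls, the highest other reaching 752, and between perilesional and nonlesional skin 1 split reached 2391, the highest other reaching 1210. The other 12 of these had 0 calls and were judged by genes with an unadjusted p under 0.05. Lesional against perilesional skin at baseline (57) was reached by 99 splits (highest other 5532), and at week 12 (72) by 97 (6143). The real grouping parts every title set, while these splits were drawn without regard to the sets. Lesional and perilesional libraries of a set deviated together (median r 0.61 at baseline and 0.57 at week 12). That lowers the real count against the splits, so this comparison cannot judge a difference between these sites. Week 12 against baseline was reached by 76 splits in lesional (401; highest other 6862), 77 in perilesional (481; 5254) and 32 in nonlesional skin (1326; 6262). Week 12 lesional against nonlesional (2383) was reached by 8 (5226) and perilesional against nonlesional (2503) by 9 (4894). Week 4 against baseline was reached by 5 splits in lesional (3181; 5829), 57 in perilesional (707; 6324) and 95 in nonlesional skin (204; 5816). The contrasts of week 12 changes were reached by 81 splits (458; 5469) in lesional and 85 (540; 5790) in perilesional skin. Splits with several times the real count point to a structure of the samples, whose source was not tested. For week 12 lesional against perilesional skin, where the title sets pair the libraries, 100 splits that part all 9 pairs were also compared, with the sets as a block. They differ from the real one in having lesional and perilesional libraries exchanged in some sets. The real number of genes with an unadjusted p under 0.05 (339) was reached by 63 of them (highest other 4186, median of the others 472), so chance was not excluded.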
